A study of Mus musculus with 2 samples.

How the data were processed

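Single-cell RNA was measured in 2 libraries of carotid arteries taken 18 hours after injury, 1 per group, each a pool of arteries of 1 genotype per the labels' protocols, after a short enzymatic digest, red cell lysis and freezing. The deposited values are UMI counts per gene and barcode, per the file headers made with Cell Ranger 8.0.1; STAR, with no version, and the mm10 build are named in the submitters' processing notes. Each barcode in the files had at least 501 UMIs, so a cell call preceded deposit, and cell types were assigned here from the counts. Both tables list the same 32285 genes, of which 40 identifiers share a symbol with a more abundant one and were kept apart by identifier.

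Cells with at least 300 genes and at most 15% mitochondrial UMIs were kept. Of the control barcodes 224 had too few genes and 335 exceeded the mitochondrial limit, against 255 and 348 in the knockout library. Cells were ranked per library by the share of simulated doublets among their neighbours, and the number removed was set by an assumed rate of 0.008 per 1000 cells, not by a score limit; this took out 363 control (5.39%) and 476 knockout cells (6.17%). Counts were scaled to the cell total and logged, the 2000 most variable genes (Gja1 left out) were reduced to 30 principal components, and a graph of 20 neighbours was clustered with the Leiden method at resolution 1.0, which gave 24 clusters. A cluster was called X-like from cell type markers fixed before the data were examined, with at least 3 detected, and stayed unnamed where its 10 leading genes held more markers of another type, or where its cells were shallow, at a median depth under 1/3 of that of their library, and none of its own markers was among those 10. Merging monocytes with macrophages, and T with NK cells, was decided after seeing the data. EC-like cells came from 1 deep and 1 shallow cluster in both libraries and were clustered again at resolution 0.6, and at 0.3 and 1.0, where the Ano1 and Procr state appeared too. A subcluster led by leukocyte genes (81 control and 77 knockout cells) was shallow.

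Counts were summed per class and library and given as CPM of the class total. Log2 ratios are knockout over control, and a gene with fewer than 3 UMIs in a library took 3 there. Poisson intervals are exact, ratio intervals are the exact conditional binomial ones, shares have exact Clopper-Pearson binomial intervals and share ratios Katz intervals, all at 95%. Shares of cells with UMIs were compared after thinning to 1000 UMIs. Gene lists fixed before the data were examined were summarised by the median log2 ratio of members with at least 20 UMIs, with its percentile among 10000 random lists matched in 20 bins of mean expression and intervals from Poisson draws of the counts, as a description of these libraries. Members count as higher or lower at a log2 ratio of at least 0.58 in size. No test between groups was made, since 1 library per group allows none.

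The genes named in EC-like cells were Gja1, the 12 highest and the 12 lowest log2 ratios among genes with at least 100 UMIs, detected in at least 5% of cells of the library with more, and at least as abundant in the class as outside it. Mitochondrial, ribosomal, haemoglobin and sex-linked genes and unnamed gene models were left out of that ranking. Up to 4 members with at least 50 UMIs were taken per list, and in other classes of at least 100 cells per library 5 genes each way. Lipg, Cdh1, Slc7a2 and the others named there follow this rule, while Mki67, Top2a and the Xist and Y-linked splits were chosen after the values were seen. Positions come from the GRCm38 annotation.

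Alternatives were tried for the gene and mitochondrial limits, doublets, clustering, scaling, free RNA and the rules above. Free RNA, estimated from marker genes in classes that should lack them, had a median share of 4.94% of the library profile in the control and 3.58% in the knockout library, and the subtraction rests on these medians. The pairs spread widely: B-cell markers gave 112% and 104% in SMC-like and 219% and 213% in fibroblast-like cells, carried by Ebf1 at 1312 and 1382 CPM in the latter, which is not free RNA. In EC-like cells B-cell markers gave 15.9% and 20.7% and neutrophil markers 5.74% and 3.05%. Without B-cell markers, a choice made after seeing the data, the medians were 3.74% and 3.38%. On data simulated from the EC-like sums, scored over 8284 genes with at least 100 UMIs, 98% of 2-fold and 100% of 4-fold genes passed the size threshold in the right direction. Of unchanged genes, 0.619% passed it in either direction. These counts were Poisson draws from 1 shared profile, without spread between cells or animals, so the percentages cover counting error only. The percentages do not hold for list members below 100 UMIs, which enter from 20. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.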

Results

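Injured mouse carotid arteries were dissociated 18 hours after a temporary ligation, and the messenger RNA of single cells was counted from its 3′ ends with molecular identifiers (UMIs). The control library came from pooled arteries of mice that carried the floxed connexin 43 gene without Cre. The EC-Cx43-KO library came from pooled arteries of mice with a Cre driven by the endothelial Cdh5 promoter, designed to remove connexin 43 in endothelial cells (EC). Each group had 1 library. The control library held 7298 barcodes and 48862850 UMIs, and the EC-Cx43-KO library 8315 barcodes and 54392831 UMIs, with medians of 4483 and 4590 UMIs per barcode. After filtering, 6376 control and 7236 knockout cells were kept. With 1 library per group no difference has a replicate check. Intervals are at 95% and cover counting error only; those of gene list medians come from Poisson resampling of the counts, those of share ratios are Katz intervals and the others are exact.

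The first comparison concerns the target itself, Gja1, which encodes the gap junction protein connexin 43. By summed counts, Gja1 differed by less than its counting error between the EC-like cells of the libraries. The control library gave 87 Gja1 UMIs in 482 EC-like cells, or 21.2 CPM (counts scaled to a class total of 1e6; Poisson interval 16.9 to 26.1). The EC-Cx43-KO library gave 86 UMIs in 551 EC-like cells, or 20.9 CPM (16.7 to 25.8), a log2 ratio of -0.02 (-0.47 to 0.43). Several other classes held more Gja1, control and knockout: 267 and 262 CPM in fibroblast-like cells, 134 and 123 CPM in smooth muscle cell (SMC)-like cells, and 43.2 and 47.3 CPM in monocyte/macrophage-like cells. Whether the Cre acted in any of these classes is not given by the labels. Neutrophil-like cells were at 5.11 and 8.18 CPM. Gja1 (ENSMUSG00000050953) lies on chromosome 10 from 56377330 to 56402513 on the plus strand of GRCm38 (mm10), and its main transcript has its coding sequence, from 56387547 to 56388692, in exon 2 with the 3′ UTR from 56388693 to 56390415. A 3′ tag outside the deleted part checks nothing, and neither the labels nor the count tables say which part was removed or where the tags lie, so these counts do not check the genotype labels. The ratio was 0.51 with doublets kept and -1.17 as a ratio of mean single-cell CPM.

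**Figure D1:**
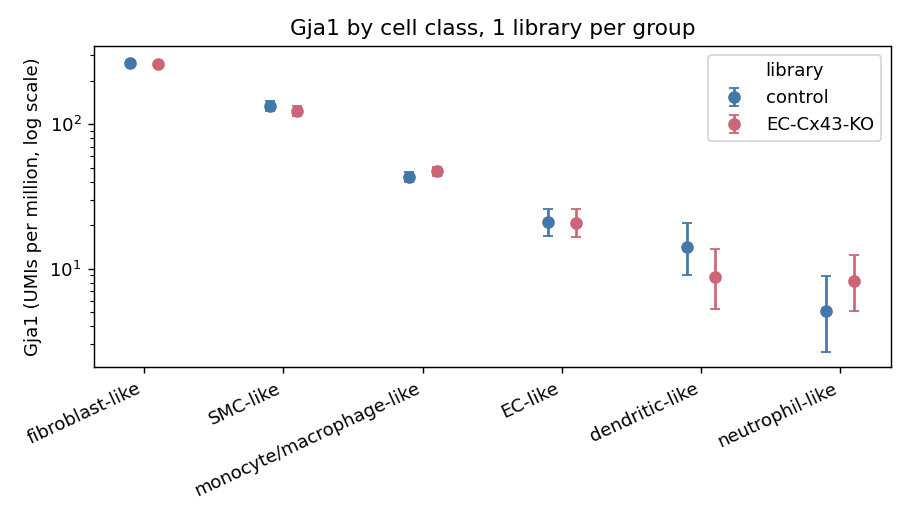
Gja1 in CPM (log axis) by cell class in the control and EC-Cx43-KO libraries; points are class sums of 1 library each and bars exact 95% Poisson intervals. EC-like cells sit at 21.2 and 20.9, below the fibroblast-like cells at 267 and 262.

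Within the EC-like cells, Gja1 was high in 1 state and in a small capillary-like group. A subcluster led by Ano1, Procr, Ccnd1, Plat and Hbegf, found without Gja1 among the clustering genes, held 51 of 482 control cells (10.6%, binomial interval 7.98% to 13.7%) and 53 of 551 knockout cells (9.62%, 7.29% to 12.4%). Gja1 stood at 60.7 CPM there in the control library and 86.7 CPM in the knockout library. The EC-like cells outside this state and outside a small capillary group were at 4.94 and 3.87 CPM, so that the state was 12.3-fold (6.90 to 23.1) above them in the control library and 22.4-fold (12.1 to 44.6) in the knockout library. Those other cells held 16 and 13 Gja1 UMIs and stood no higher than neutrophil-like cells, at 5.11 and 8.18 CPM. B-cell-like cells were at 6.55 and 7.03 CPM, from 2 and 3 UMIs. T/NK-like cells were lower, at 0 and 1.80 CPM from 0 and 1 UMIs, but with upper interval ends of 7.13 and 10.0 CPM. The folds are therefore over cells not shown to hold Gja1 above the level of free RNA. The capillary-like subcluster, led by Fabp4, Cd36, Igfbp3 and Gpihbp1, stood highest, at 621 CPM (380 to 960) in the control and 148 CPM (84.4 to 240) in the knockout library, but these are 20 UMIs in 6 control cells and 16 UMIs in 29 knockout cells, too few cells to compare. After thinning each cell to 1000 UMIs, 2.10% (0.966% to 3.95%) of control and 0.81% (0.221% to 2.06%) of knockout EC-like cells had a Gja1 UMI, against 0.493% and 0.764% of neutrophil-like cells, and 54 and 57 shallower EC-like cells were left out. At 500 UMIs, with no cell left out, the EC-like shares were 1.04% and 0.907%, 5 cells in each library. At 2000 UMIs they were 3.54% (1.95% to 5.88%) and 1.56% (0.63% to 3.18%), and the neutrophil-like ones 1.16% and 1.28%. Without thinning the EC-like shares were 7.88% and 7.44%, at median depths of 6324 and 6047 UMIs, and the neutrophil-like shares 1.09% and 1.54%, at 1848.5 and 1677.5 UMIs. The thinned shares rest on few cells and their intervals overlap, so no order is read from them.

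**Figure D2:**
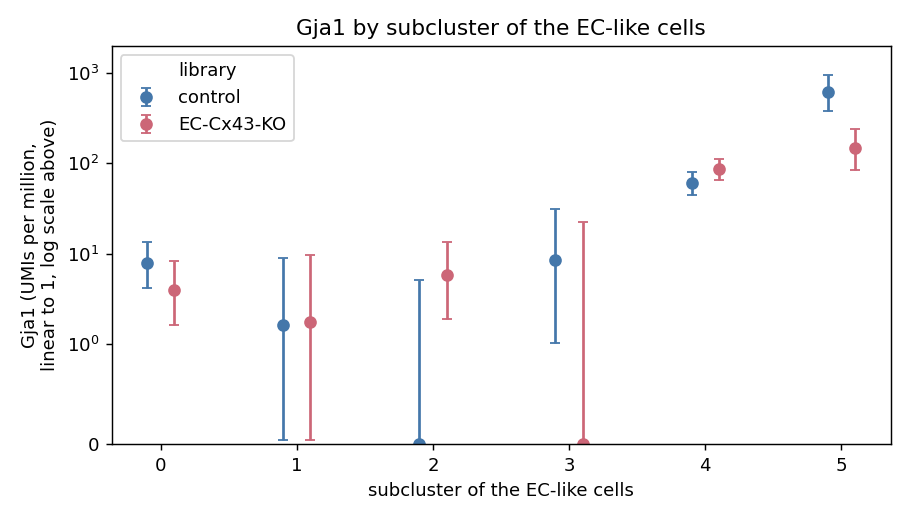
Gja1 in CPM (linear to 1, log scale above) by subcluster of the EC-like cells in both libraries; points are sums over the subcluster's cells and bars exact 95% Poisson intervals. Subcluster 4, the Ano1 and Procr state, stands at 60.7 and 86.7, and subcluster 5 is the capillary-like group with 6 and 29 cells.

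The second comparison asks whether the injured artery held other cells in the knockout. EC-like cells made up the same share of both libraries, 7.56% (binomial interval 6.92% to 8.24%) of control and 7.61% (7.01% to 8.25%) of knockout cells. Fibroblast-like cells were at 22.1% and 22.4% and neutrophil-like cells at 17.3% and 17.9%. Monocyte/macrophage-like cells were fewer in the knockout library, 36.3% against 33.4% (log2 ratio -0.12, Katz interval -0.19 to -0.05), and SMC-like cells more, 6.35% against 7.41% (0.22, 0.04 to 0.40). B-cell-like cells were at 1.47% and 2.06% (0.48, 0.11 to 0.85), T/NK-like cells at 1.87% and 2.13%, dendritic-like cells at 3.40% and 3.10%, and platelet-like cells, shallow at medians of 776 and 879.5 UMIs, were 13 and 58 cells (1.98, 1.11 to 2.84). The platelet-like difference depended on the filters. With at least 500 genes per cell, platelet-like cells were 8 of 6048 control and 10 of 6802 knockout cells. With doublets kept they were 29 of 6739 and 60 of 7712 cells. Haemoglobin RNA was higher in the knockout library as well, 596 against 1526 CPM in EC-like cells, 494 against 1537 CPM in neutrophil-like cells, 29.7 against 255 CPM in monocyte/macrophage-like cells and 14.6 against 2930 CPM in dendritic-like cells. A shallow unnamed cluster held 3.50% of control and 3.21% of knockout cells. At a clustering resolution of 2.0 the monocyte/macrophage ratio turned to 0.026, with 846 control and 676 knockout cells left unnamed, and was -0.12 there with clusters named by marker score alone, a setting chosen after seeing the data. The short digestion, pooling and freezing can set shares as well as the genotype can.

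The third comparison asks how gene programmes of the EC-like cells differed. Genes of endothelial identity had a median log2 ratio of 0.04 over 25 members, with 2 higher and 0 lower by 1.5-fold or more. The adhesion molecules and chemokines of activated endothelium had a median of 0.04 over 24. Their members went both ways, with 2 higher and 2 lower, the latter being Cd74 and Ccl2, given below. The genes induced by laminar flow had a median of -0.00 over 22, with 0 higher and 1 lower. The gap junction list, of connexins, pannexins and the scaffold gene Tjp1 (-0.11), had a median of -0.08 over 6 members, with Gja5, the connexin of arterial endothelium, at 745 against 585 CPM (-0.35, -0.43 to -0.27), Gja4 at -0.05 and Gjc1 at 0.23. Adherens and tight junction genes had a median of -0.11 over 23, none of them 1.5-fold higher or lower. DNA replication genes had a median of -0.00 over 33 and mitosis genes -0.11 over 25, with 3 members higher and 3 lower by 1.5-fold or more. Among 10000 random lists matched on expression, these medians lay at percentiles 88.0, 94.6, 64.5, 37.4, 9.67, 80.6 and 21.8, in the order given. Of EC-like cells thinned to 1000 UMIs, 26.6% of control and 24.9% of knockout cells had at least 3 cell cycle UMIs, against 18.5% and 14.1% of neutrophil-like cells, which do not divide. The proliferation genes Mki67, with 7 UMIs in each library, and Top2a, with 21 and 28 (0.41, -0.46 to 1.30), had too few UMIs for a precise ratio.

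Several lists had medians below that of all genes in EC-like cells of the knockout library, in part as in other classes. The coagulation and thrombosis list had a median of -0.18 over 15 members (percentile 0.76), with Plat, the tissue plasminogen activator, at -0.69 (351 against 217 CPM), and Procr, the protein C receptor, at -0.57. Its median was as low in SMC-like cells (-0.18, percentile 2.02) and in fibroblast-like cells (-0.21, percentile 0.49), but not in monocyte/macrophage-like (0.026, percentile 73.5), neutrophil-like (-0.06, percentile 52.0) or T/NK-like cells (0.16 over 4 members, percentile 79.7), and it was -0.28 (percentile 15.3) in dendritic-like cells. Plat and Procr are among the genes that lead the Gja1-high state, whose cells gave 20.4% of the EC-like UMIs in the control library and 16.0% in the knockout library. Purinergic and calcium signalling genes had a median of -0.17 over 20 (percentile 1.44), with the calcium channel Trpv4 at -0.58 and the calcium release receptor Itpr3 at -0.46. YAP targets had a median of -0.16 over 16 (percentile 1.76), none of them 1.5-fold apart. Mesenchymal genes linked to endothelial-to-mesenchymal transition had a median of -0.14 over 20 (percentile 5.63). It was -0.074 with members of at least 1 UMI and also under median-of-ratios scaling, which shifts all genes alike. Acta2 was at -0.94 and Tagln at -0.77. Both also belong to the SMC contractile list, whose median in EC-like cells was 0.24 over 15 members. Basement membrane and matrix genes had a median of -0.13 over 21 (percentile 3.43), against -0.17 in SMC-like cells, and hypoxia genes -0.16 over 16 (percentile 6.65). The growth factor gene Areg was at 100 against 9 UMIs (-3.48), in a list of angiogenesis genes with a median of -0.10, while in dendritic-like cells Areg was higher in the knockout library (1.57). The invariant chain gene Cd74 (-1.91) and the chemokine gene Ccl2 (-1.08) were lower in the knockout library too, beside the neutrophil genes S100a8 (-1.03) and S100a9 (-0.83). Ccl2, S100a8 and S100a9 are among the leading genes of the leukocyte-led EC-like subcluster, which gave 233977 control and 165137 knockout UMIs. At resolution 1.0 a subcluster led by Chil3, Spp1 and Arg1 held 30 control and 6 knockout cells. Whether the differences in these genes lie in endothelial cells was not tested.

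A few genes of capillary endothelium and fatty acid uptake were higher in EC-like cells of the knockout library, while the list of lipid uptake and cholesterol genes had a median of 0.07 (interval -0.10 to 0.25, percentile 96.5), with 6 of 20 members higher and 0 lower. Fabp4, a fatty acid binding protein of capillary endothelium, was at 112 against 631 CPM (log2 ratio interval 2.35 to 2.64), with Cd36 at 1.83, Lpl at 1.88 and Gpihbp1 at 1.58. The Fabp4 ratio was 0.42 when cells with up to 25% mitochondrial UMIs were kept and 0.49 without the capillary-like subcluster, and that of Kdr, the main VEGF receptor, which was 1.01, became 0.36 and 0.34. With doublets kept the ratios were 3.34 for Fabp4 and 2.08 for Kdr, as mean single-cell CPM 3.31 and 1.84, and at 500 genes per cell, with clusters named by marker score alone, 3.51 and 1.84. The other genes highest by the naming rule were Ecrg4 (1.26), Rasl11a, Tmem252, Prelid2, Cmtm8, Ifi27l2b, Gin1, Apold1, Ppip5k1 and Smyd4 (the last at 0.83). Without the capillary-like subcluster Tmem252 went from 1.01 to 0.050 (-0.52 to 0.62) and Apold1 from 0.86 to 0.22 (-0.20 to 0.65). The lowest were Fam199x (-1.11), Dand5, Tmem132a, Prx, Nptx1, Fbxl18, Trim69, the lysosomal regulator Tfeb, Ptchd1, Igtp, H2-Q6 and Tcf23 (-0.80), of which Fam199x and Ptchd1 lie on chromosome X. The stress gene Gdf15 was at 30 against 126 UMIs (2.07) in a list of p53 and apoptosis genes with a median of 0.01. Ribosomal protein genes had a median of 0.21 and nuclear respiratory chain genes 0.15, against -0.06 over the 11845 genes measured in EC-like cells. The same lists were higher in SMC-like (0.15 and 0.19), fibroblast-like (0.18 and 0.23), monocyte/macrophage-like (0.19 and 0.15), dendritic-like (0.36 and 0.33) and neutrophil-like cells (0.41 and 0.24), and in T/NK-like cells they were at 0.09 and 0.006 (percentiles 81.6 and 77.4). Of the 24 genes named by rank, 11 were named again with doublets kept and 8 when single-cell CPM were averaged.

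The fourth comparison asks which differences appear in classes other than the EC-like cells. The labels do not say whether the Cre acted in any of them, blood cell classes included. Interferon-response genes were higher in the knockout library in SMC-like, monocyte/macrophage-like, fibroblast-like, neutrophil-like and dendritic-like cells, while the differences in EC-like and T/NK-like cells were small. The list had a median of 1.74 in SMC-like cells (27 of 29 members at least 1.5-fold higher), 1.12 in monocyte/macrophage-like cells (28 of 31), 1.04 in fibroblast-like cells (23 of 30), 0.96 in neutrophil-like cells (25 of 29), 0.62 in dendritic-like cells (15 of 28), 0.27 in EC-like cells (interval 0.05 to 0.32; 10 of 31, with 2 lower) and 0.10 in T/NK-like cells (-0.11 to 0.51; 8 of 23, with 2 lower). The EC-like median was 0.088 (-0.047 to 0.265) once free RNA was subtracted and 0.057 over members with at least 100 UMIs. In EC-like cells Isg15 was at 20.7 against 66.5 CPM (1.69) and Ifit3 at 11.2 against 36.4 CPM (1.70). In monocyte/macrophage-like cells the chemokine gene Cxcl10 was at 57.8 against 529 CPM (3.19) and the antiviral gene Rsad2 at 96.8 against 550 CPM (2.51). Over all kept cells this difference went with the sex of the cells, though not alike in every class. Kept cells were split by Xist UMIs, from the X chromosome of female cells, and UMIs of 4 Y-linked genes; cells with both kinds (2.26% of control and 2.24% of knockout cells) or with neither (30.4% and 32.6%) were left out. Free RNA alone would give an Xist UMI to 11.1% of control and 6.08% of knockout cells and a Y-linked one to 3.01% and 2.90%, so the split is not clean. Over kept cells with Xist UMIs the list median was 1.53 (Poisson resampling interval 1.43 to 1.60), and its summed level was 2182 CPM in the control and 5872 CPM in the knockout library. Over kept cells with Y-linked UMIs the median was -0.35 (-0.38 to -0.22), at 3192 and 2979 CPM. With at least 2 UMIs of one kind and none of the other, a limit chosen after seeing the data, the medians were 1.52 (1.40 to 1.55) and -0.29 (-0.36 to -0.18). In EC-like cells the medians were 0.50 with Xist and -0.12 with Y-linked UMIs, and in fibroblast-like cells 2.14 and -0.40. SMC-like cells (2.59 and 0.52) and neutrophil-like cells (1.44 and 0.40) were above 0 in both. Under the limit of at least 2 UMIs, SMC-like cells were at 2.43 and 0.64. Neutrophil-like cells were then at 0.79 (0.38 to 1.29, 8 members) and 0.64 (0.36 to 1.13, 15 members), with little difference by sex. EC-like (0.49 and -0.04) and fibroblast-like cells (2.12 and -0.32) changed little under that limit. The libraries differed in their mix: 1164 of 6376 control and 1962 of 7236 knockout cells had Y-linked and no Xist UMIs, and Xist in EC-like cells was at 229 against 123 CPM. This holds beside each difference in EC-like cells above, and animal and genotype cannot be separated with 1 pool each.

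**Figure D3:**
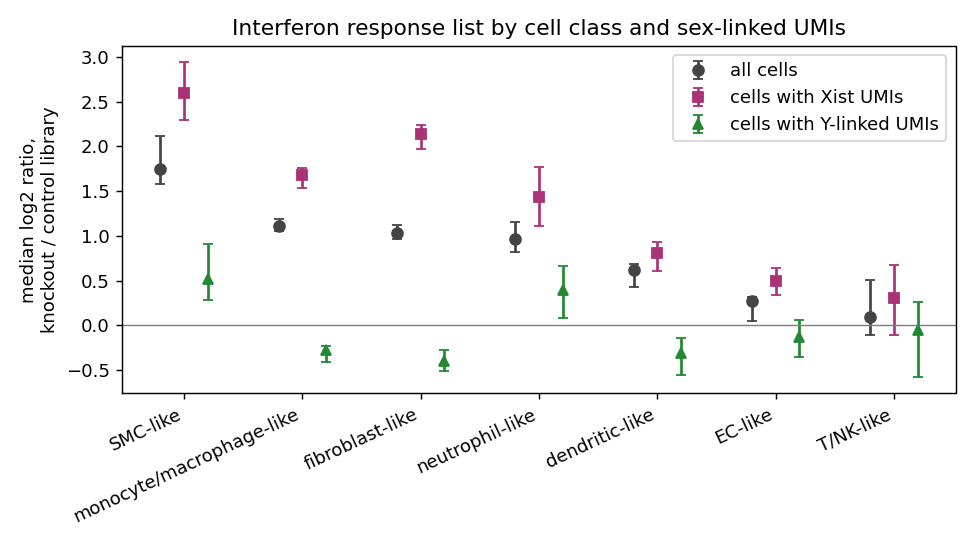
Median log2 ratio (knockout over control library) of the interferon response list by cell class, over all cells, cells with Xist and no Y-linked UMIs, and cells with Y-linked and no Xist UMIs; bars are 95% intervals from Poisson resampling of the counts. Fibroblast-like cells stand at 1.04 over all cells, 2.14 with Xist UMIs and -0.40 with Y-linked UMIs.

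Other genes differed in single classes. Monocyte/macrophage-like cells, held mostly by a Spp1 and Arg1 cluster and a Fabp5 cluster in the control library but by the former and an interferon-led Ly6c2 cluster in the knockout library, had lower Lpl (-1.13), Slc7a2 (212 against 106 CPM) and Cdh1 (-1.22), and more of the lipase gene Lipg (1.03 against 40.9 CPM). Dendritic-like cells of the knockout library had less, by the naming rule, of the chemokine genes Ccl22 (-2.10) and Ccl17 (-1.60), the chemokine receptor gene Ccr7 (-1.89), Il4i1 (-2.42) and Pdcd1lg2 (-1.48), beside the difference in haemoglobin RNA given above. That class held 217 control and 224 knockout cells, but 87 and 88 at a clustering resolution of 2.0. Another mix of cells within it cannot be told apart from lower levels per cell. In T/NK-like cells the granzyme gene Gzma was at 906 against 66.4 CPM (-3.77) and Il18rap was at -1.79. This class joined a cluster named NK, which also held T-cell markers (81 control and 107 knockout cells), and one named T-cell (38 and 47). The leading genes of the latter include Arpp21, Myb, Themis, Ccr9, Rag1 and Dntt. Whether its cells are mature T cells of the artery was not tested. The share of NK cells within the cluster named NK was not measured, so these ratios need not be differences within a cell type. Fibroblast-like cells had lower Saa3, an acute phase protein (578 against 237 CPM, -1.28), and Tmem267 (-2.71), with a median of -0.18 over the fibroblast activation list. In SMC-like cells the contractile list (0.07 over 20 members, 0.03 to 0.09, percentile 96.5) and the modulated list (-0.16 over 23, -0.20 to -0.09, percentile 0.52) lay on either side of the median over all genes (-0.03), both by little. Activation genes of neutrophils had a median of 0.31 over 21 members in neutrophil-like cells and maturation genes -0.25 over 17. The make-up of the class differed too: a cluster led by Retnlg and S100a8 held 585 of 1102 control and 575 of 1298 knockout cells, and one led by Hcar2 and Ccl3 159 and 256, so these medians need not be differences within a cell state.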

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

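The settings without the capillary-like, shallow or leukocyte-led EC-like cells, those with clusters named by marker score alone, 2 other free RNA shares, and the interferon list in other classes were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The cause of a moved value was not tested unless given. The Gja1 ratio in EC-like cells stayed within its counting interval under 16 settings and moved to 0.51 with doublets kept and to -1.17 as mean single-cell CPM, which weights shallow cells like deep ones. Class shares kept their direction or interval in 64 of the values tried, which cover classes with at least 100 cells in each library. B-cell-like, platelet-like and unnamed cells were therefore not among them. The monocyte/macrophage ratio reversed to 0.026 at resolution 2.0, and was -0.12 there with clusters named by marker score alone.

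For endothelial identity the median was -0.026 at up to 25% mitochondrial UMIs, 0.077 with doublets kept and 0.10 under median-of-ratios scaling. That scaling also gave leukocyte adhesion 0.11, EndMT -0.074, flow response 0.062, interferon response 0.34 and, reversed, the mitochondrial genome list 0.024. It shifts the log2 ratios of all genes of a class by the same amount. Values moved by it, here and in other classes, therefore leave each list in its place relative to all genes. Interferon response was 0.088 with free RNA subtracted, 0.088 with a share estimated without B-cell markers, 0.100 with that from neutrophil markers in EC-like cells (which gave EndMT -0.049) and 0.057 over members with at least 100 UMIs. Flow response was -0.069 with doublets kept. Mean single-cell CPM gave gap junction -0.31, leukocyte adhesion -0.089 and flow response -0.094, and list members with at least 1 UMI gave EndMT -0.074. The interferon median in other classes moved in dendritic-like cells to 0.69 with doublets kept and 0.73 under median-of-ratios scaling, in fibroblast-like cells to 1.13 at up to 25% mitochondrial UMIs, and in monocyte/macrophage-like cells to 1.20 under median-of-ratios scaling and 1.20 as mean single-cell CPM. Of the 24 genes named by rank, 11 were named again with doublets kept, 8 by mean single-cell CPM, 11 at 50 UMIs or more and 9 at 200 UMIs or more.

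The share with at least 3 cell cycle UMIs follows depth by construction: control and knockout were at 7.88% and 5.99% thinned to 500 UMIs, 64.6% and 65.6% at 2000, and 84.0% and 82.8% unthinned, while at least 2 UMIs gave 49.1% and 49.0% and at least 5 gave 5.37% and 4.66%. The share with a Gja1 UMI was 1.04% and 0.907% thinned to 500 UMIs, 3.54% and 1.56% at 2000 and 7.88% and 7.44% unthinned. No value was had for EC-like cells at 500 genes under the naming rule, for T/NK-like and dendritic-like cells at 10% mitochondrial UMIs, or for dendritic-like cells at resolution 2.0 and with at least 2 own markers. By counting error alone, the 87 and 86 Gja1 UMIs place the EC-like log2 ratio within -0.47 to 0.43. They came from 38 control and 41 knockout cells, with up to 8 and 13 in 1 cell. That interval leaves out spread between cells and is therefore too narrow.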

Other observations

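Of the tests below, only the one of free interferon RNA was fixed before its result was seen; the split by sex, the Gja1 tests and the capillary tests were chosen after, and the capillary test was tried in 3 forms, all given.

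Resident macrophages, a cluster led by Lyve1, Cd163, C1qa and Folr2, made up 4.63% (3.81% to 5.56%) of monocyte/macrophage-like cells in the control library, 107 of 2313, and 11.6% (10.3% to 12.9%) in the knockout library, 279 of 2415. Their Cd163 level was alike, 1843 and 1874 CPM, and Lyve1 was at 1327 and 945 CPM. In both libraries they held more cells with Y-linked and no Xist UMIs (41.1% and 42.7%) than their class as a whole (15.4% and 24.0%). The list of inflammatory macrophage genes had a median of 0.32 over 19 members in the class and the list of resident and repair genes 0.19 over 24.

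The interferon-response genes were higher in EC-like cells of the knockout library by a median of 0.27. After subtraction of the free RNA profile the median was 0.088 (-0.047 to 0.265), so free RNA from interferon-high monocytes cannot be told apart from expression in these cells, because the interval includes 0; with the share taken without B-cell markers, chosen after seeing the data, it was 0.088 (-0.052 to 0.261). Over all kept cells the lower of the medians by sex was -0.35 (-0.38 to -0.22), in cells with Y-linked and no Xist UMIs. It was 1.53 with Xist and no Y-linked UMIs. With at least 2 such UMIs, since free RNA blurs the split, the medians were -0.29 and 1.52. Over all kept cells this fits a response in the female animals of the knockout pool, or in some of them. However, SMC-like (0.52) and neutrophil-like cells (0.40) with Y-linked UMIs were higher in that library too, and both were at 0.64 with at least 2 such UMIs. In neutrophil-like cells the median with Xist UMIs was 1.44, and 0.79 with at least 2, so that class does not show the split clearly. Genotype acting in 1 sex and other differences between single animals stay open as untested, since each genotype has 1 pool.

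Gja1 stood at a like level in EC-like cells of both libraries by summed counts (-0.02), but not as mean single-cell CPM (-1.17) or with doublets kept (0.51), so the level itself is uncertain. Over all EC-like cells, free RNA from fibroblasts as its only source is argued against by the Gja1 to Pdgfra ratio. It was 17.1 times (9.66 to 32.6) that in fibroblast-like cells in the control library and 16.6 times (9.22 to 32.5) in the knockout library. Most Gja1 UMIs came from the Ano1 and Procr state (51 and 57) and the capillary-like group (20 and 16). The other EC-like cells held 16 and 13, at 4.94 and 3.87 CPM, against 5.11 and 8.18 CPM in neutrophil-like cells. For those other EC-like cells free RNA is not argued against, and a loss of Gja1 in them would be hard to see. Without the capillary-like subcluster the ratio was 0.087 (-0.42 to 0.59). Since that subcluster held 20 control and 16 knockout Gja1 UMIs, leaving it out could not lower the ratio. For the summed counts, down to the lower end of the interval, those UMIs argue against a surplus of capillary cells that hides a loss elsewhere. Most remaining Gja1 UMIs came from the Ano1 and Procr state, so a loss in the other EC-like cells is not covered. Whether the 3′ tags lie outside the deleted part cannot be told apart from an incomplete deletion, because the gene table has 0 columns of tag positions. A transcript that is kept without its coding part may therefore give these counts.

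Fabp4 and Kdr were higher in EC-like cells of the knockout library, the former at 112 against 631 CPM and the latter by a log2 ratio of 1.01. Without the capillary-like subcluster (6 and 29 cells), which Fabp4 helped to define, they were 0.49 and 0.34. Without a subcluster found with both genes left out, which had 87 and 107 cells and was not a clean capillary group, they were 0.11 and 0.38. Without cells that held at least 2 other capillary markers (11 and 21 cells) Fabp4 was 1.25 (0.98 to 1.53) and Kdr 0.29, a median of 0.77, so that more capillary cells in the knockout library may account for Kdr, and for Fabp4 cannot be told apart from a higher level per cell, because so few cells carry the markers.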
